A study of Mus musculus with 13 samples.

How the data were processed

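Single-colour Cy5 arrays read at 635 nm were analysed from the scanner output and the table of values deposited by the authors. Per the file headers each array holds 27456 spots, of which 2736 are blank spots and 24 are copies of a positive control, and RNA had been amplified as amino allyl aRNA and coupled to the dye. The scanner output at 3 gains carries no background correction. The intensity unit of the deposited value table was not stated by the authors and was inferred from the values: each column is a straight line of the spot median, less the middle of the blanks and multiplied so that the median is 25. The number of cells, the sex of the animals, the purity after sorting and the time in culture of the GMTMM and MT iCMs are not given in the sources used here. Whether the probes for the transduced factors also read vector transcripts is not given in the sources used here either.

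The median of each spot was corrected by normexp with an offset of 50, without subtracting the local surround, since the surround followed the spot signal (r 0.893 to 0.966 on the log2 scale). Spots marked as not good by the scanner (0 to 6 per array) were set to missing. Values were put on the log2 scale, and arrays were quantile normalised over the probe spots, without blanks and positive controls. An offset of 50 compresses differences of dim genes. A probe lay well above background when its spot exceeded the blank mean by 2 SD. The blank mean was 13.1 to 15.4 in the array series of the GMT iCMs and 39.9 to 41.1 in that of the TTFs, GMTMM and MT iCMs. The coefficient of variation was 5.90% to 17.6% for 1 positive control and 5.77% to 16.5% for another, and 0 to 1 probes per array reached the limit of 65535.

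Of 23473 probes 16631 carried 1 gene symbol and 6842 carried none. Of the symbols 12622 were current, 3947 were updated to a current symbol and 62 had no match. The brightest probe stood for each of 16390 genes. Actc1, Nkx2-5 and Mef2c are not named in the probe table and were not analysed here, so 11 of the 14 panel genes were measured. The 31 fixed lists held 515 genes, 455 of them measured. The list of transduced factors covers GMTMM, so its members Myocd and Mesp1 were not transduced in GMT iCMs. The lists were written before the data were examined.

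Medium was tested with limma (two-sided, with a mean-variance trend) on 8 iCM arrays, with context (GMT at 2 weeks, GMT at 4 weeks, GMTMM) and medium as additive terms and 3 residual degrees of freedom. The context term covers the array series. Genes well above background in at least 2 arrays of the fit were tested, and p-values were adjusted by Benjamini and Hochberg with a threshold of 0.05, over all genes and again within each list alone. The adjustment within a list makes no allowance for the number of lists or of comparisons. Genes that pass over a list alone may therefore include chance calls. Unless said otherwise, adjusted p-values are those of limma. The fitted SF difference leans partly on the FFV arrays, which is why values of the pairs are given as well. Time was tested on the 6 GMT arrays with medium and time as terms. Comparisons without a test are given as log2 differences, as counts of genes at least 2-fold apart in every pair and well above background in the higher array, and as medians of lists. List medians were placed among 10000 random lists matched for level. Beside counts over several pairs stands a chance count, the mean of 20 simulated draws with the residual scatter of the fit and no effect. The draws hold no difference between array series and treat every gene as well above background. For comparisons across series the chance count therefore does not show how many genes the series alone would part. Where every array of the lower side lay near the blanks, the fold is given as a bound with the words at least.

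Genes named in the text are a panel of 14, up to 4 members of each described list with the largest absolute difference, and the 5 highest and 5 lowest genes past the threshold, or at least 2-fold apart the same way in every pair and ranked by the smallest difference. Predicted genes without a name of their own were passed over. The test was tested on simulated data: with 15246 genes and 100 changed genes of each size, 87.0% of 2-fold and 99.0% of 4-fold changes were recovered, with 5 false among 191 calls. The simulated changes were equal in every context, with normal scatter of the fitted size. These shares therefore do not hold for genes whose response to medium differs between contexts, and a gene not called may still have changed. The Benjamini and Hochberg limit also loosens as more genes are called, with 191 calls here and 6 in the real FFV against FBS fit. At the stricter limit of the real fit the recovered shares would be lower, also for equal changes, and they were not measured.

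Alternatives fixed at the start were median scaling, an offset of 16, a floor on blank-subtracted signal, the deposited value table, no filter on dim genes or one on all arrays, no trend, the mean over probes, leaving out each context, medium or array, the 6 GMT arrays alone, FFV and FBS arrays alone with and without context as a block, thresholds of 3-fold and 1.5-fold, TTFs in place of MEFs, the heart of the same series and Spearman correlation. Added after seeing the data were subtraction of the local surround before normexp, the probes without a gene name, and the counts of lists under each setting. Left out were the unnamed probes from every named result. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with matplotlib 3.10.9 were used.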

Results

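Gene expression was measured in mouse cells on 13 single-colour Cy5 arrays, 1 array per group, so there were no replicate cultures or animals. The series asks how cardiac reprogramming proceeds under defined culture conditions. Induced cardiomyocyte-like cells (iCMs) are fibroblasts driven towards a heart muscle state by transduced transcription factors. Of the arrays, 6 held iCMs made with GMT (Gata4, Mef2c and Tbx5) and sorted for a GFP reporter of the cardiac αMHC promoter, in 3 media at 2 and 4 weeks. The media were FBS (with serum), SF (serum-free) and FFV (FGF2, FGF10 and VEGF). A further 2 arrays held iCMs from tail-tip fibroblasts (TTFs) made with GMTMM (GMT plus Mesp1 and Myocd) in FFV and in FBS, and 1 held iCMs made with MT (Mef2c and Tbx5) in FFV. The labels give neither a time nor a sort for these 3. Hearts of embryonic day 12 (E12) and postnatal day 1 (P1), mouse embryonic fibroblasts (MEFs) and TTFs gave 1 array each. Between 78.4% and 91.5% of the 23473 probes per array lay well above the blank spots, and the median signal was 1.54 to 3.46 times the blank mean. The number of arrays limits the precision of every comparison. Array identifiers fell into 3 series: the GMT iCMs with the E12 heart, the MEFs with the P1 heart, and the TTFs with the GMTMM and MT iCMs.

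The GMT iCMs resembled one another more than any other group, and the GMTMM iCMs lay closest to the TTFs. Pearson correlations across genes were 0.970 to 0.995 among the 6 GMT arrays, 0.922 to 0.941 between these and the MT iCMs, and 0.879 to 0.914 between these and the MEFs. They were 0.874 to 0.895 between GMT iCMs and the E12 heart and 0.873 to 0.888 between GMT iCMs and the P1 heart. GMTMM iCMs correlated with TTFs at 0.956 and 0.958. Genes are not independent replicates, so these coefficients carry no test. In the plot of principal components the hearts stood apart on the second axis, and the GMT iCMs stood apart from both fibroblasts on the first.

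**Figure D1:**
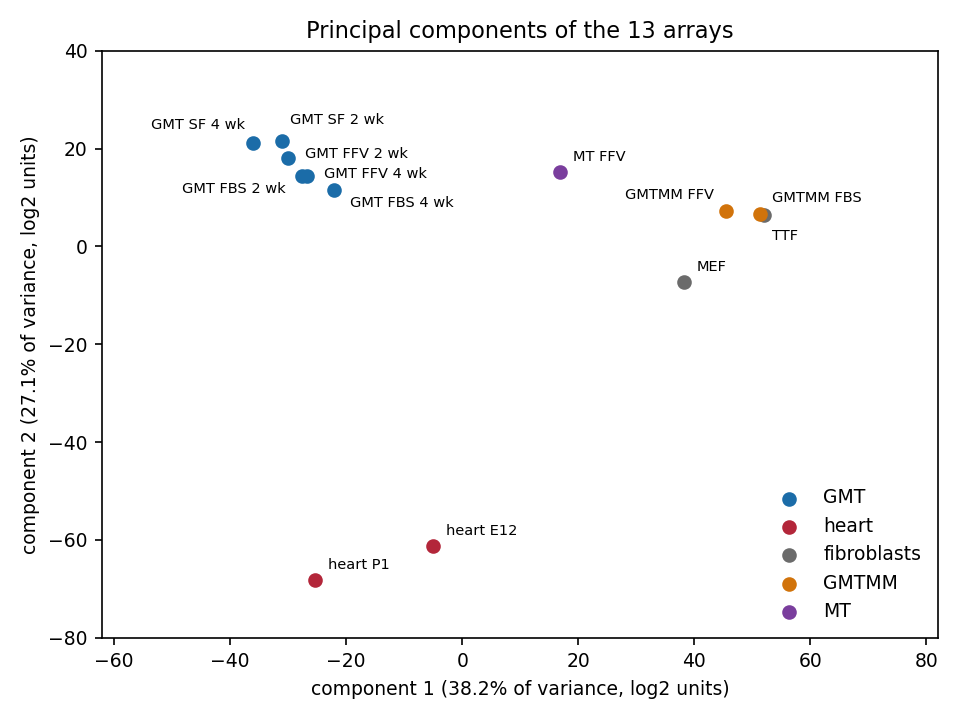
Principal components of log2 normalised intensity over the 13 arrays, 1 point per array, with the first component (38.2% of variance) on the x axis and the second (27.1%) on the y axis. GMT iCMs lie between -36.0 and -22.2 on the first axis, TTFs at 52.0, and the hearts at -61.1 (E12) and -68.1 (P1) on the second.

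GMT iCMs were compared with MEFs, the cells of origin, to ask which genes differ after reprogramming. Sarcomere genes were far higher in the iCMs, with a median log2 difference of 3.79 over 24 measured genes, 17 of them at least 2-fold higher in all 6 arrays and 0 lower. The atrial light chain Myl7 was 747-fold higher, cardiac troponin T (Tnnt2) 230-fold and the α-myosin heavy chain Myh6 52.4-fold. The muscle LIM protein Csrp3 was at least 258-fold higher, a bound because the MEF signal lay near the blank spots. Both natriuretic peptides were higher, Nppa 46.8-fold and Nppb 13.5-fold. The transduced factors Gata4 (118-fold) and Tbx5 (67.1-fold) were higher. The list of cardiac regulators beyond these had a median of 0.05, although Ankrd1 was 110-fold higher.

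Genes of fatty acid oxidation were higher in GMT iCMs than in MEFs (median 0.76 over 22 genes, 5 at least 2-fold higher), led by the thiolase Acaa2 at 23.0-fold and the dehydrogenase kinase Pdk4 at 10-fold. Oxidative phosphorylation genes had a median of 0.64 and glycolysis genes one of 0.42. Calcium handling genes were higher by a median of 0.68, with the sarcoplasmic reticulum pump Atp2a2 5.33-fold and the calcium buffer Casq2 at least 7.79-fold higher. The ryanodine receptor Ryr2 was at least 2.91-fold higher, and the pump inhibitor Pln had a log2 difference of 0.08. Ion channels had a median of 0.08.

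Fibroblast and matrix genes were lower in GMT iCMs than in MEFs (median -2.19), 23 of 33 by at least 2-fold in all 6 arrays. Periostin (Postn) was 30.8-fold lower, the collagens Col1a1 24.7-fold and Col3a1 12.6-fold, and smooth muscle actin Acta2 2.71-fold. TGF-β and myofibroblast genes (median -0.78), inflammatory secreted factors (-0.77), interferon response genes (-1.10), sterol synthesis genes (-0.49) and amino acid stress genes (-0.73) were also lower. Of 26 cell cycle genes 8 were at least 2-fold lower (median -1.14), among them Top2a, the mitotic topoisomerase, at 4.63-fold. Macrophage markers were lower by a median of -3.38, and the complement gene C1qa was 32.1-fold lower. In all, 306 genes were at least 2-fold higher and 455 lower in all 6 arrays, where simulated scatter with no effect and no difference between array series gave 1.75 on average. The lowest of these included the retinoid-binding Crabp1 (60.9-fold), the growth factor Ptn (60.2-fold), Ccn3 (33.8-fold) and the cell cycle inhibitor Cdkn1c (28.0-fold). No test was possible with 1 array per group, the 6 differences share the MEF array, and array series and cell type cannot be told apart here. As the GMT iCMs were sorted for the αMHC reporter, selection by the sort cannot be told apart from reprogramming either. With the local surround subtracted, an alternative chosen after seeing the data, the total fell to 506.

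**Figure D2:**
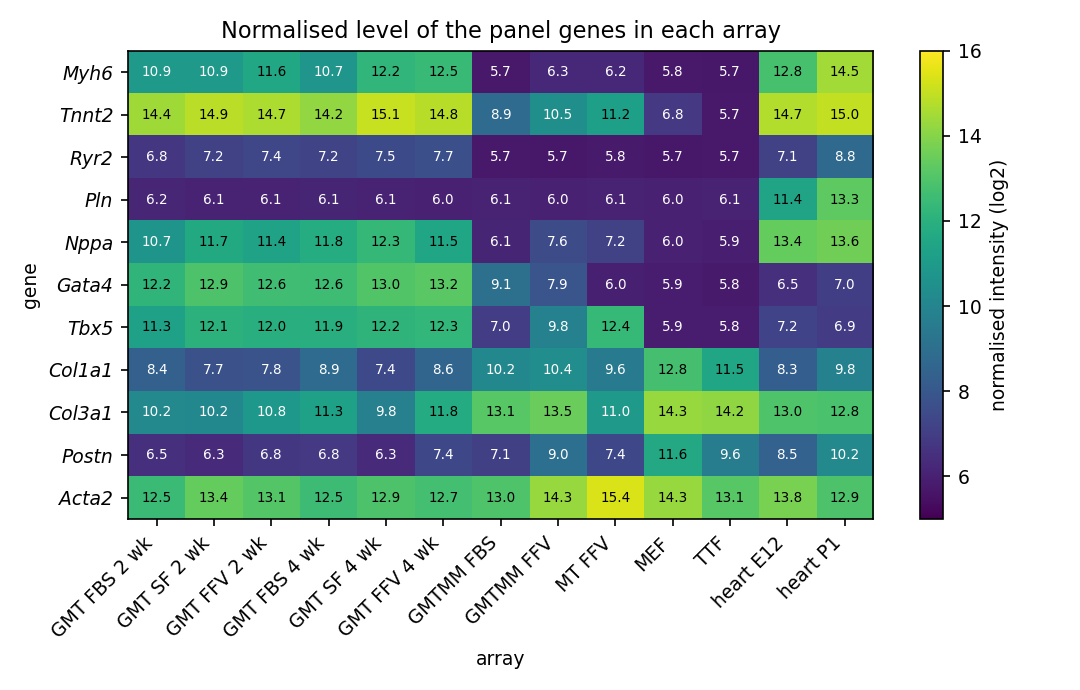
Log2 normalised intensity (colour) of the 11 measured panel genes (y axis) in each of the 13 arrays (x axis). Myh6 averaged 5.71 log2 units higher in the 6 GMT iCM arrays than in MEFs and 1.33 log2 units below the E12 heart, given as -1.33 for GMT iCMs minus E12 heart.

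GMT iCMs were compared with the hearts to place them against cardiac tissue. The hearts were tissue, and the GMT iCMs were cultured cells sorted for the αMHC reporter. For both hearts, cell composition, sort and culture therefore cannot be told apart from the cardiac state. Against the E12 heart the 24 sarcomere genes had a median difference of -0.41, which turned to 0.06 with the local surround subtracted. Tnnt2 had a log2 difference of -0.07 from the E12 heart, Myh6 was 2.51-fold lower, and the ventricular light chain Myl2 was 486-fold lower on average, with its signal near the blank spots in 1 of the 6 iCM arrays. The embryonic troponin Tnni1 was 26.9-fold lower and Pln 40.8-fold lower, whereas the M-band protein Myom2 was 39.0-fold higher. Of the sarcomere genes, 9 to 11 per array lay within 2-fold of the E12 heart and 4 to 6 within 2-fold of the P1 heart. For the 18 sarcomere genes at least 4-fold higher in the E12 heart than in MEFs, iCMs covered a median of 77.4% of that log2 difference in FBS at 2 weeks and 97.7% in FFV at 4 weeks. The range over the 6 arrays was 26.0% to 65.4% for 4 calcium handling genes, 10.8% to 46.3% for 4 of oxidative phosphorylation, 4.00% to 20.7% for 6 regulators and -0.06% to 2.02% for 3 ion channels. The median difference of 15 calcium handling genes from the E12 heart was -0.00, with 2 to 4 per array at least 2-fold lower and 0 to 2 higher.

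Cardiac regulators were lower than in the E12 heart (median -0.78, 8 of 17 at least 2-fold), including Gata6 (20.4-fold) and the homeodomain protein Hopx (15.9-fold). Gata4 and Tbx5 were 76.0-fold and 26.8-fold higher. Cell cycle genes were lower by a median of -2.55, 24 of 26 at least 2-fold, with the proliferation antigen Mki67 11.4-fold lower. Endothelial genes were lower too (median -1.51), as the receptor kinase Tie1 at 21.9-fold. Genes of the p53 response were higher (median 1.66, 6 of 10 at least 2-fold), led by the cell cycle inhibitor Cdkn1a at 28.0-fold. Oxidative phosphorylation genes had a median of -0.29, which turned to 0.17 with median scaling and 0.08 with a floor. Fatty acid oxidation genes stood at -0.19, turning to 0.22, 0.26 and 0.17 with median scaling, a floor and the deposited value table. Glycolysis genes stood at -0.36, turning to 0.10 and 0.01 with median scaling and a floor. Of 1073 genes at least 2-fold apart in all 6 arrays, 498 were higher in iCMs (46.4%). That share was 67.5% with median scaling, 61.3% with a floor and 56.8% with the value table. The surface protein Ly6c1 (87.8-fold) and the calcium-binding S100a6 (67.9-fold) were among the highest.

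Against the P1 heart the iCMs were lower in sarcomere genes (median -1.58), oxidative phosphorylation (-1.58, 29 of 37 at least 2-fold) and fatty acid oxidation (-2.03, 19 of 22). Myoglobin (Mb) was 150-fold, muscle creatine kinase (Ckm) 123-fold, the fatty acid transporter Cd36 42.5-fold and Myh6 8.02-fold lower. Calcium handling genes had a median of -1.07 with Pln 143-fold lower, ion channels one of -0.34 and regulators one of -1.09. Endothelial genes were lower (median -1.91), with the tight junction gene Cldn5 at least 39.1-fold lower. The p53 list was higher (median 2.08), as were sterol synthesis genes (0.69), and tropomyosin Tpm1 was 15.4-fold higher. Of 1098 genes at least 2-fold apart in all 6 arrays 41.9% were higher in iCMs, a share of 73.7% with median scaling, 64.1% with a floor and 61.3% with the value table. The E12 heart shares the array series of the GMT iCMs and the P1 heart does not.

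FFV and FBS cultures were compared across the 3 contexts in which both were grown (GMT at 2 weeks, GMT at 4 weeks, GMTMM), to ask what the defined medium changes. Of 15246 genes, 2 rose and 4 fell in FFV, all at an adjusted p of 0.0418 and in the same direction in 3 of 3 pairs. The myosin light chain Myl1 rose by a log2 difference of 2.78 ± 0.20 (SE) and Sel1l3 by 1.91 ± 0.15. The surface glycoprotein Thy1, a fibroblast marker, fell by 1.96 ± 0.15, the sterol exporter Abcg1 fell by 1.85 ± 0.15, the junction protein F11r fell by 1.58 ± 0.12 and the steroid dehydrogenase Hsd3b6 fell by 0.73 ± 0.05. Hsd3b6 was dim, with a mean log2 level of 6.16 where the lowest level on these arrays was 5.65. The offset therefore compresses its difference and its SE. At an unadjusted p under 0.05 there were 1635 genes. The p-values rest on scatter of the medium effect between contexts, not between replicate cultures. The 6 calls became 0 without either GMT time, 0 without a mean-variance trend, 0 with a floor and 0 with the local surround subtracted, and 621 without the GMTMM arrays. With the surround subtracted the Thy1 difference at 4 weeks turned to 1.07.

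In the fixed lists, sarcomere genes were higher in FFV for 19 of 24 members, and adjusted over the list alone 6 rose, 0 fell and 18 did not pass. Among those that rose were titin (Ttn, 1.01 ± 0.17) and α-actinin 2 (Actn2, 0.92 ± 0.23), while Myh6 stood at 0.99 ± 0.31 and Tnnt2 at 0.81 ± 0.27 without passing. Of 16 glycolysis genes 14 were lower and 7 fell, including the lactate exporter Slc16a3 (-2.15 ± 0.35), hexokinase Hk2 (-1.12 ± 0.23) and the glucose transporter Slc2a1 (-0.89 ± 0.15). All 13 macrophage markers were lower and 10 fell, including C1qb (-2.92 ± 0.68), C1qa (-2.74 ± 0.52) and the Fc receptor chain Fcer1g (-2.35 ± 0.57). Over all genes tested, limma called 0 members of each of these 3 lists, with 12, 10 and 11 members at an unadjusted p under 0.05. The sarcomere count became 0 without the GMT 2-week or 4-week arrays, 0 without a trend, 0 with the surround subtracted, 2 with a floor and 11 without GMTMM. The glycolysis count became 3 without the 2-week arrays, 0 without the 4-week arrays and 1 with the surround subtracted. The macrophage count became 0 without the 4-week arrays, 0 without a trend and 5 with a floor.

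Smaller parts of other lists changed, adjusted over the list alone. The VEGF receptor Flt1 rose by 1.25 ± 0.15, the regulator Gata6 by 0.67 ± 0.14, the cofactor Zfpm2 by 0.48 ± 0.12 and the potassium channel Kcnq1 by 0.52 ± 0.09. Connexin 43 (Gja1) fell by 0.75 ± 0.16 and the potassium channel Kcnh2 fell by 0.60 ± 0.14. Matrix genes gave 1 rise (Mgp, 1.07 ± 0.20) and 1 fall (Thy1), and TGF-β genes gave 2 rises (Ccn2, 1.14 ± 0.24; Tgfb3, 0.74 ± 0.14). Single falls came from the antiviral Bst2 (-0.97 ± 0.13), the cytokine Il33 (-1.27 ± 0.21), the tubulin Tubb3 (-0.96 ± 0.18), osteopontin Spp1 (-1.26 ± 0.24) and Rpl14 (-0.65 ± 0.12). In the skeletal muscle list Myl1 and Mylpf (0.55 ± 0.12) rose and 2 genes fell, among them Acta1 (-0.45 ± 0.12). Limma called 0 genes over the list alone for oxidative phosphorylation (5 unadjusted), fatty acid oxidation (6), calcium handling (3), natriuretic peptides (0), transduced factors (2), smooth muscle (2), cell cycle (0), sterol synthesis (0), FGF and ERK feedback (1), p53 (1), amino acid stress (4), erythroid (0), epicardial (3), adipocyte (1), epithelial (0), posterior Hox (2) and anterior Hox genes (0).

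FFV and FBS were also compared pair by pair. At least 2-fold apart were 176 genes in GMT iCMs at 2 weeks (97 higher in FFV), 279 at 4 weeks (107 higher) and 484 in GMTMM iCMs (276 higher). The order is not settled, since with the local surround subtracted the counts were 464, 499 and 468. All 3 pairs shared 10 higher and 10 lower genes, against 0.700 from simulated scatter. The effects correlated across genes at 0.67 between the GMT times and at 0.08 and 0.09 between GMTMM and these (Spearman 0.54, -0.03 and -0.09). At 4 weeks the highest genes included Ndrg4, a cytoplasmic protein of heart and brain (16.1-fold), and Corin, the protease that activates natriuretic peptide (9.39-fold), with Myh6 3.34-fold higher. The secretogranin Scg2 was 10.2-fold and C1qa 11.1-fold lower. In GMTMM iCMs the lipocalin Lcn2 was 40.8-fold, the cartilage protein Comp 19.0-fold, complement C3 14.2-fold and Myl7 4.76-fold higher, with C1qb 24.5-fold and Slc16a3 8.63-fold lower. Sarcomere medians were 0.29, 0.46 and 0.25 in the 3 pairs, glycolysis medians -0.44, -0.46 and -0.46, and macrophage medians -0.24, -0.97 and -2.17. Matrix genes had medians of 0.11, 0.09 and 0.36.

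**Figure D3:**
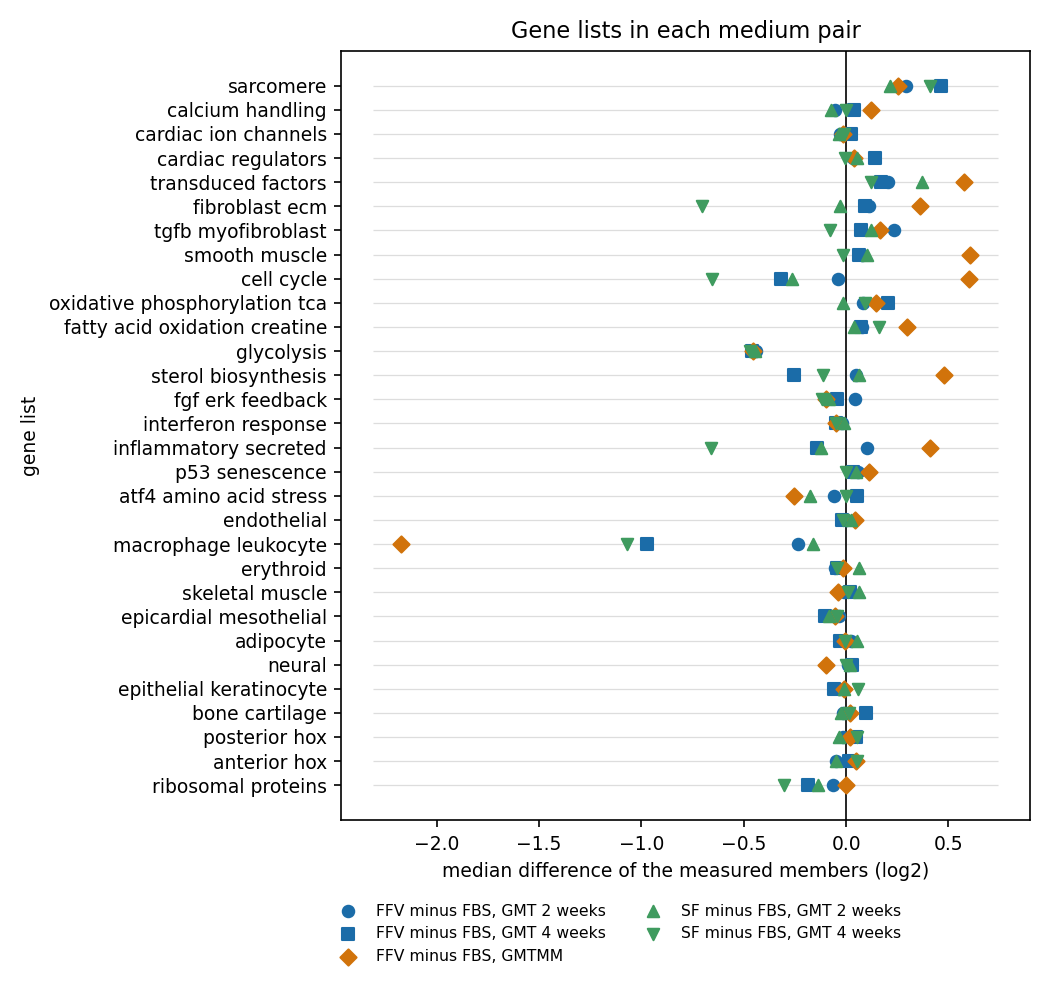
Median log2 difference (x axis) of 30 fixed gene lists (y axis) in 5 pairs of media, 1 point per pair, GMT iCMs at 2 and 4 weeks and GMTMM iCMs. Glycolysis genes lie at -0.44, -0.46 and -0.46 for FFV minus FBS and macrophage markers at -0.24, -0.97 and -2.17.

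When the same fit was made on the 6 GMT arrays alone, medium separated many more genes. FFV against FBS then gave 266 genes that rose and 355 that fell of 15037, all 6 genes named above among them. Ndrg4 rose by 3.84 ± 0.17 at an adjusted p of 0.00146, in 2 of 2 pairs, followed by Tcp11x2 (2.99), Corin (2.84) and the ADP-ribosyltransferase Art3 (2.72). Scg2 fell by 3.30 ± 0.11, Phlda2 fell by 2.87 and the lipid carrier Apoe fell by 2.40. Of 24 sarcomere genes 6 rose and 2 fell over all genes tested, and 4 of 16 glycolysis genes fell. With 2 residual degrees of freedom, the spread behind these calls is the scatter between 2 and 4 weeks.

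SF and FBS were compared in GMT iCMs to ask what removing serum does without the added factors. Of 15246 genes 3 rose and 4 fell. Sel1l3 rose by 2.30 ± 0.18 (adjusted p 0.0379), integrin α8 (Itga8) by 1.68 ± 0.14 (0.0491) and the transporter Slc6a18 by 0.65 ± 0.05 (0.0333). Thy1 fell by 3.19 ± 0.18 (adjusted p 0.0284), the chaperone clusterin (Clu) fell by 2.83 ± 0.20 (0.0333), the creatine synthesis enzyme Gatm fell by 1.69 ± 0.14 (0.0488) and Hsd3b6 fell by 0.78 ± 0.06 (0.0333), each in both pairs. Slc6a18 and Hsd3b6 were dim, with mean log2 levels of 6.07 and 6.16 where the lowest level on these arrays was 5.65. At an unadjusted p under 0.05 there were 1984 genes. These 7 calls became 0 without either GMT time, 0 without a trend, 0 with the surround subtracted and 2 with a floor, and 1653 without the GMTMM arrays, with all 7 among them.

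Adjusted over the list alone, 4 sarcomere genes rose in SF, among them Myoz2 (1.60 ± 0.24), Ttn (1.35 ± 0.20) and Myom2 (0.99 ± 0.25), and 2 fell, among them Tnni1 (-1.22 ± 0.22). Glycolysis gave 5 falls of 16, including Hk2 (-1.62 ± 0.27), Slc16a3 (-1.74 ± 0.41) and the kinase Pgk1 (-0.97 ± 0.20). Ion channels gave 4 falls and 1 rise, with Kcnj8 at -1.36 ± 0.26 and Gja1 at -1.67 ± 0.18, the mean of whose pairs turned from -1.75 to 0.06 with the surround subtracted. Matrix genes gave 3 falls, Thy1, decorin (Dcn, -1.57 ± 0.20) and lumican (Lum, -1.20 ± 0.27), a count of 10 without the GMT 2-week arrays, 1 without the 4-week arrays, 6 without GMTMM and 0 with the surround subtracted. Flt1 (1.58 ± 0.17) and Tgfb3 (1.04 ± 0.16) rose, and Il33 (-2.08 ± 0.25), Spp1 (-2.03 ± 0.28), Tgfbi (-1.75 ± 0.38) and Bst2 (-0.87 ± 0.15) fell. The p53 targets Ccng1 (0.68 ± 0.16), Zmat3 (0.58 ± 0.14) and Phlda3 (0.47 ± 0.14) rose. Of 13 macrophage markers 12 were lower and 2 fell, C1qa by a log2 difference of -2.58 ± 0.61. Over all genes, limma called 0 sarcomere, 0 glycolysis and 0 macrophage genes, with 9, 9 and 8 at an unadjusted p under 0.05. Without the GMT 4-week arrays the sarcomere, glycolysis and macrophage counts became 0, and without the 2-week arrays the sarcomere count became 0, the glycolysis count 2 and the macrophage count 10. Without GMTMM these 3 counts became 9, 10 and 10.

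Cell cycle genes were lower in SF than in FBS for 24 of 26 members without a call over the list alone (4 at an unadjusted p under 0.05 in limma), with Top2a at -1.09 over its pairs. In the fit to the 6 GMT arrays 15 of them fell over all genes tested and 20 over the list alone. There were 178 genes at least 2-fold apart in both pairs, 73 higher and 105 lower in SF, against 6.4 from simulated scatter. By log2 difference the highest were Ndrg4 (4.14) and Tcp11x2 (3.90) and the lowest Scg2 (-3.66) and Apoe (-3.60). The effect of SF at 2 weeks correlated across genes with that of FFV at 4 weeks at 0.72, and the effect of SF at 4 weeks with that of FFV at 2 weeks at 0.56, pairs that share no array.

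FFV and SF were compared in GMT iCMs to ask what the 3 added factors do in the absence of serum. Limma called 0 of 15246 genes, with 768 at an unadjusted p under 0.05 and a lowest adjusted p of 0.112. Matrix genes were higher in FFV for 27 of 32 members, and adjusted over the list alone 9 rose and 1 fell. Col1a2 rose by 1.94 ± 0.36, Dcn by 1.58 ± 0.20, Col6a1 by 1.51 ± 0.32 and the metalloproteinase Mmp2 by 1.39 ± 0.26. Col3a1 rose by 1.30 ± 0.34, although the mean of its pairs turned from 1.34 to -0.48 with the surround subtracted. The matrix count of rises became 0 without the GMT 4-week arrays, 0 with the surround subtracted, 3 with a floor, 14 without the 2-week arrays and 11 without GMTMM. Gja1 (0.91 ± 0.18), Gata6 (0.68 ± 0.16), the Notch target Hey2 (0.38 ± 0.07), Atf3 (2.31 ± 0.53), Atf4 (0.58 ± 0.14) and Trp63 (0.77 ± 0.13) rose over their own lists. Macrophage markers had medians of 0.0032 at 2 weeks and -0.01 at 4 weeks for FFV minus SF. The fitted values, which lean on the GMTMM pair, were lower in FFV for 12 of 13 (median -0.21), with 0 called by limma over the list alone and 0 at an unadjusted p under 0.05.

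At least 2-fold apart in both FFV and SF pairs were 34 genes higher in FFV and 2 lower, against 6.20 from simulated scatter. Among the highest were the growth factor Ptn (5.18-fold), the stress factor Atf3 (4.85-fold), the nuclear receptors Nr4a1 (4.20-fold) and Nr4a2 (3.32-fold) and the AP-1 component Jun (3.60-fold). In the FGF and ERK feedback list the log2 difference of Fos stood at 1.68, Egr1 at 1.60 and the ERK phosphatase Dusp6 at 0.60, and limma called 0 of 17 over the list alone (2 unadjusted). Cell cycle genes were higher for 25 of 26 members with 0 called (2 unadjusted). The lowest gene with a known cardiac role was Casq2 at a log2 difference of -1.16, and the mitochondrial coactivator Ppargc1a stood at 1.10.

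The 4-week and 2-week GMT iCMs were compared across the 3 media to ask what changes with time. Limma called 0 of 15037 genes, with 1322 at an unadjusted p under 0.05 and a lowest adjusted p of 0.550. Adjusted over the list alone, Actn2 rose by 0.92 ± 0.15, both natriuretic peptides rose (Nppa 0.63 ± 0.19, Nppb 0.45 ± 0.15), and the lipase Lpl (0.74 ± 0.10) and Ppargc1a (0.64 ± 0.11) rose, each higher in 3 of 3 media. Myh6 stood at 0.66 ± 0.27. Of 16 sterol synthesis genes 15 were lower and 5 fell, among them the demethylase Cyp51 (-0.51 ± 0.11) and mevalonate kinase (Mvk, -0.40 ± 0.12). Glycolysis genes gave 3 rises, Pfkl (0.48 ± 0.09) and Pgk1 (0.39 ± 0.10) among them. Gja1 fell by 0.55 ± 0.11, S100a4 fell by 0.65 ± 0.11, Cdkn2a fell by 0.64 ± 0.14, Myc fell by 0.41 ± 0.09 and Nes fell by 0.41 ± 0.09. Epor (0.36 ± 0.06), Myl1 (0.67 ± 0.13), Gap43 (0.36 ± 0.10) and Col2a1 (0.86 ± 0.22) rose. The sterol count became 0 without SF, 0 without FFV, 0 with the value table or the surround subtracted and 2 with a floor, and the glycolysis count became 0 without FBS, without SF or with the surround subtracted, 1 with median scaling or a floor and 5 with the value table. Without the SF arrays 7 genes rose over all genes tested. The median of all genes was 0.14 in the value table and -0.0024 with quantile scaling. No gene was at least 2-fold apart in all 3 media, and in single media 68 genes were higher and 6 lower at 4 weeks in FBS, 44 higher and 20 lower in FFV, and 5 higher and 4 lower in SF. Macrophage markers had medians for 4 minus 2 weeks of 0.72 in FBS, -0.04 in SF and -0.04 in FFV, and limma called 0 of 12 over the list alone (0 at an unadjusted p under 0.05).

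GMTMM iCMs were compared with TTFs, their cells of origin and of the same array series. Tnnt2 was at least 15.2-fold higher and Ankrd1 9.19-fold higher, but 1 of 24 sarcomere genes was at least 2-fold higher in both arrays (median 0.32). Myh6 lay near the blank spots in TTFs and in GMTMM iCMs in FBS, and in FFV it was at least 1.44-fold higher than in TTFs. The transduced factors Gata4 and Tbx5 were 6.49-fold and 5.98-fold higher. Mesp1 and Myocd, which set GMTMM apart from GMT, were measured too, but their values are not given here. Cell cycle genes were higher by a median of 1.36, 15 of 26 at least 2-fold, as the survivin gene Birc5 at 7.04-fold and Mki67 at 5.13-fold. Inflammatory secreted factors were higher (median 1.11), led by serum amyloid Saa3 at 37.3-fold and the chemokine Cxcl1 at 9.36-fold. Glycolysis genes (median 0.78), smooth muscle genes (0.53), TGF-β genes (0.30) and FGF and ERK feedback genes (0.24) were higher. Matrix genes were lower (median -0.32), with Col1a1 2.36-fold lower, and the senescence gene Cdkn2a was 7.73-fold lower. Macrophage markers lay at -1.45 in FFV and 0.50 in FBS. Of 291 genes at least 2-fold apart in both arrays 155 were higher, a share of 53.3% that was 68.9% with the surround subtracted, 48.0% in the value table and 49.7% at 1.5-fold, against 19.5 from simulated scatter.

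MT iCMs were compared with GMT iCMs in FFV to ask what differs when Gata4 is left out. Gata4 was 121-fold lower and Tbx5 had a log2 difference of 0.26. Sarcomere genes were lower by a median of -2.26, 14 of 24 at least 2-fold in both arrays, with Csrp3 170-fold, Myh6 55.3-fold and Tnnt2 11.4-fold lower. Nppa was 19.1-fold lower, Ankrd1 52.8-fold, Myl1 33.6-fold and Acaa2 21.6-fold. Fatty acid oxidation (median -0.74), oxidative phosphorylation (-0.52), calcium handling (-0.21) and p53 genes (-0.68) were lower. Matrix genes were higher (median 1.21, 18 of 33 at least 2-fold), as were inflammatory factors (1.07), smooth muscle genes (0.62) and cell cycle genes (0.52). Thy1 was 49.4-fold, Saa3 21.4-fold, Acta2 5.68-fold and Gata6 4.81-fold higher. Of 717 genes at least 2-fold apart from both GMT arrays 59.0% were higher in MT iCMs, a share of 34.8% in the value table, where the median of all genes was -0.11 against 0.0026 with quantile scaling. Array series and factor set cannot be told apart. The GMT iCMs were sorted for the αMHC reporter, and the labels give neither a sort nor a time for the MT iCMs. Sort and time therefore cannot be told apart from the factor set either. The fibroblast source of the MT iCMs is not stated here, so a difference in source cannot be told apart from it as well. MT iCMs covered a median of 22.6% of the sarcomere difference between MEFs and the E12 heart.

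**Figure D4:**
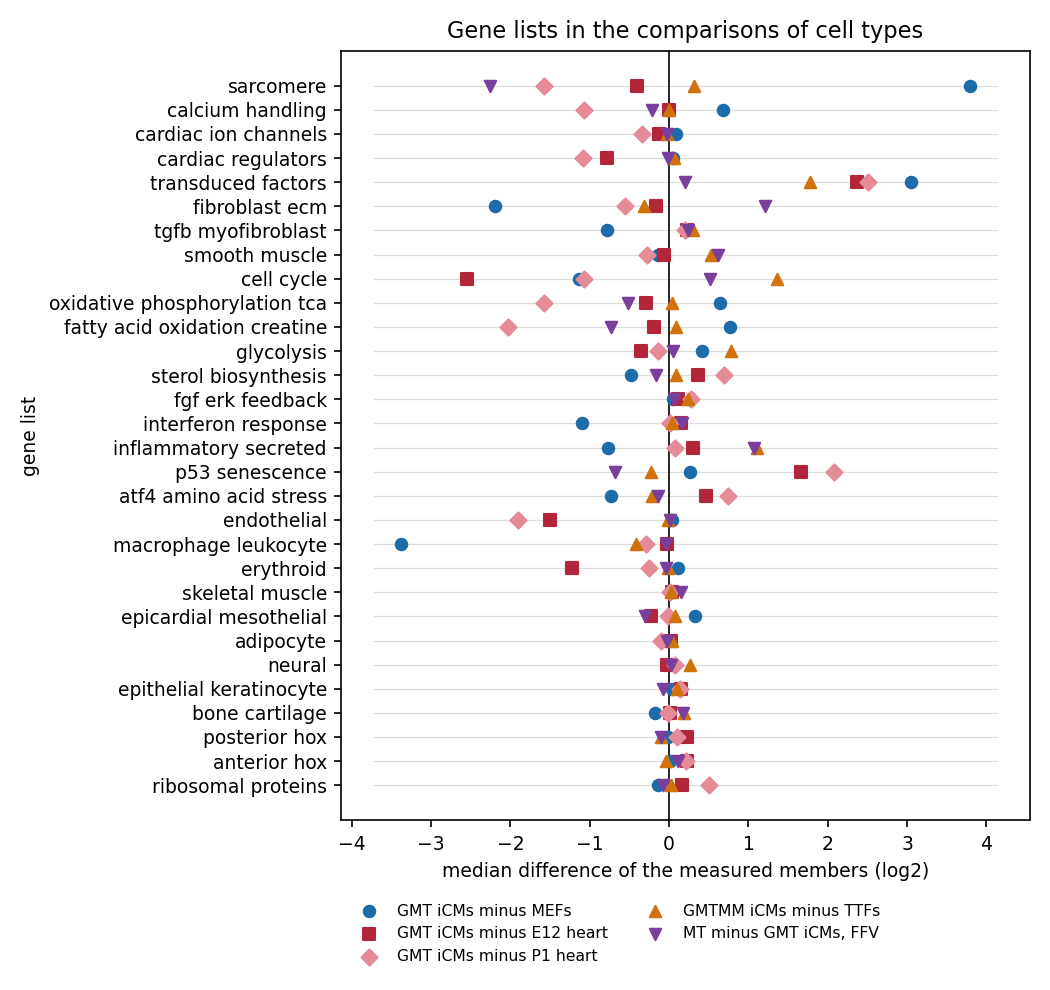
Median log2 difference (x axis) of 30 fixed gene lists (y axis) for GMT iCMs minus MEFs, minus the E12 heart and minus the P1 heart, GMTMM iCMs minus TTFs, and MT minus GMT iCMs, 1 point per comparison. Sarcomere genes lie at 3.79, -0.41 (0.06 with the local surround subtracted), -1.58, 0.32 and -2.26 in that order.

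The reference arrays differed by age and origin. In the P1 heart against the E12 heart, fatty acid oxidation genes were higher (median 1.99, 21 of 22 at least 2-fold), as were oxidative phosphorylation (1.21), calcium handling (0.90), sarcomere (0.44) and endothelial genes (0.44), with Ckm 47.1-fold, Cd36 21.2-fold and Myh6 3.19-fold higher. Cell cycle genes were lower (median -1.32), as the checkpoint kinase Bub1b at 4.33-fold. Outside that list the inhibitor Cdkn1c was 16.7-fold and the glucose transporter Slc2a1 11.1-fold lower. Of 3 measured erythroid genes (median -0.97) Slc4a1 and Epor were lower, each by 1.96-fold, and the haem synthesis gene Alas2 was 4.20-fold higher. Of 1379 genes at least 2-fold apart 51.8% were higher, a share of 40.8% in the value table and 65.6% at 3-fold. In MEFs against TTFs, cell cycle (median 1.18), macrophage (1.49, C1qa 4.50-fold), interferon (0.80) and sterol synthesis genes (0.64) were higher, and posterior Hox genes were lower (median -0.40) with Hoxc13 6.68-fold lower. The p53 list stood at -0.80, turning to 0.03 with the surround subtracted, with Cdkn2a 4.10-fold lower. Of 830 genes at least 2-fold apart 51.9% were higher in MEFs, a share of 34.4% to 54.0% under other settings, the lowest with median scaling. The median of all genes here was -0.13 in the value table and -0.0052 with quantile scaling. For GMT iCMs against MEFs it was 0.17 and 0.0095, and against the P1 heart it was 0.14 in the value table, 0.13 with a floor and 0.0132 with quantile scaling. Both comparisons cross array series, and no test was possible.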

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

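The tests of where each median lies among random lists were applied here after seeing the results, and the differences between groups were not tested. A list is given when its median for FFV minus FBS was of opposite sign in 2 of the 3 pairs of cultures and lay in the outer tails of the random lists in both. Cell cycle genes stood at -0.32 in GMT iCMs at 4 weeks and at 0.60 in GMTMM iCMs. Sterol synthesis genes stood at -0.25 at 4 weeks and at 0.48 in GMTMM iCMs. Inflammatory secreted factors stood at 0.10 in GMT iCMs at 2 weeks, at -0.14 at 4 weeks and at 0.41 in GMTMM iCMs, and the 2-week value turned to -0.00993 with the local surround subtracted.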

How the results depend on the processing

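Subtraction of the local surround, the unnamed probes and the list counts under each setting are tests chosen after seeing the results. With 1 array per group, the choice of background correction and the choice of contexts carry much of each count, and the cause was not tested. Median signal was 1.54 to 3.46 times the blank mean, so folds of dim genes depend on the offset. Every called gene kept its sign in the fit under every alternative in which it was tested. With the filter on all arrays 6 of the 7 genes called for SF against FBS were tested. Alternatives that would need replicate cultures, dye swaps or array files of other series were not run.

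For FFV against FBS the 6 calls became 11 with an offset of 16, 0 with a floor, 23 with the value table, 0 with the surround subtracted, 0 without a trend, 621 with the 6 GMT arrays only, and 0 and 0 with FFV and FBS arrays only, with and without context as a block. Leaving out contexts gave 0 to 621. For SF against FBS the 7 calls became 21, 2, 56, 0 and 0 with the offset of 16, the floor, the value table, the surround subtracted and no trend, and 0 to 1653 on leaving out contexts. FFV against SF went from 0 to 1 with a floor. Time went from 0 to 1 with the value table and gave 0 to 7 on leaving out media.

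Counts of genes at least 2-fold apart follow in the order offset of 16, floor, value table, surround subtracted, 3-fold and 1.5-fold where these moved. FFV against FBS at 2 weeks had 176 and went to 320, 733, 887, 464, 41 and 681, and at 4 weeks it had 279 and went to 481, 1066, 1301, 499, 73 and 1073. In GMTMM iCMs 484 went to 821, 1828, 2178 and 468, then 162 at 3-fold and 1543 at 1.5-fold. GMT iCMs against MEFs went from 761 to 1736 with a floor, 1864 with the value table, 506 with the surround subtracted, 339 at 3-fold and 1606 at 1.5-fold. Against the E12 heart 1073 went to 2349, 2385, 552, 443 and 2323 in that same order, and against the P1 heart 1098 went to 2540 with a floor, 2598 with the value table, 441 at 3-fold and 2349 at 1.5-fold. GMTMM iCMs against TTFs went from 291 to 475, 1011 and 1170 with the offset of 16, a floor and the value table, then 66 and 940 at 3-fold and 1.5-fold. MT against GMT iCMs went from 717 to 1148, 2617, 3083, 284 and 1836 in that same order. The P1 against the E12 heart went from 1379 to 2104, 3041, 3491, 393 and 3226, and MEFs against TTFs went from 830 to 1442, 3343 and 3949, 1409 with the surround subtracted, 199 at 3-fold and 2454 at 1.5-fold.

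Similarity changed less. The median correlation among GMT arrays went from 0.985 to 0.953 with the surround subtracted, that with fibroblasts from 0.895 to 0.840, and that of GMTMM iCMs with fibroblasts from 0.946 to 0.890. That of GMT iCMs with hearts went from 0.885 to 0.908 with Spearman correlation, 0.895 with an offset of 16, 0.902 with a floor, 0.906 with the value table and 0.853 with the surround subtracted.

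Signs turned mostly with the surround subtracted. For FFV minus FBS at 2 weeks the list of transduced factors, which also holds Myocd and Mesp1 that GMT lacks, went from 0.20 to -0.0333. Inflammatory factors went from 0.10 to -0.00993 there, and in GMTMM iCMs calcium handling went from 0.12 to -0.0034. Amino acid stress genes over time went from 0.14 to -0.0322, sarcomere genes against the E12 heart from -0.41 to 0.0623, and p53 genes in MEFs minus TTFs from -0.80 to 0.0261. For FFV minus FBS at 4 weeks Thy1 went from -1.68 to 1.07, Col1a2 from 1.10 to -0.0758, Idi1 from -1.10 to 0.17 and Tnnt3 from -1.17 to 0.52. Gja1 in SF minus FBS went from -1.75 to 0.0610 and Col3a1 in FFV minus SF from 1.34 to -0.48. In GMT iCMs minus MEFs Cdk1 went from -2.49 to 0.0407 and Fcer1g from -4.68 to 0.60, and minus the E12 heart Cdk1 went from -3.44 to 0.88. Aurka in P1 minus E12 went from -1.63 to 0.0370. In MEFs minus TTFs Tbx3 went from -1.57 to 0.0140, Inhba from -2.35 to 0.0454, Acadm from 1.03 to -0.44 and Mdm2 from -1.18 to 2.10.

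With other settings, ribosomal genes in SF minus FBS went from -0.20 to 0.0300 with a floor. Against the E12 heart oxidative phosphorylation went from -0.29 to 0.17 with median scaling and 0.0833 with a floor, fatty acid oxidation from -0.19 to 0.22 with median scaling, 0.26 with a floor and 0.17 with the value table, and glycolysis from -0.36 to 0.10 and 0.00896 with median scaling and a floor. Oxidative phosphorylation in MEFs minus TTFs went from 0.27 to -0.0653 with a floor and -0.0299 with the value table.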

Other observations

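The tests of array scaling, of background correction, of macrophage glycolysis, of dilution and of array series below were chosen after seeing the results. MT iCMs kept part of the cardiac difference from MEFs: 13 of 24 sarcomere genes were at least 2-fold higher than in MEFs (median 1.37) and 0 lower, and 5 lay within 2-fold of the E12 heart. Genes of oxidative phosphorylation in GMT iCMs lay within 2-fold of the E12 heart for 28 to 31 of 37 members and within 2-fold of the P1 heart for 3 to 7. For fatty acid oxidation the counts were 14 to 16 of 22 and 1 to 2. Of the sarcomere difference between MEFs and the P1 heart, GMT iCMs covered a median of 61.7% in FBS, 65.9% in SF and 67.0% in FFV at 2 weeks, and 61.4%, 74.3% and 76.9% at 4 weeks.

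Macrophage markers were lower in FFV than in FBS, most of all in GMTMM iCMs and at 4 weeks. Fewer macrophages among the cells are a candidate source: a second macrophage list, 13 of whose 16 genes were measured, had medians of -0.18, -0.61 and -1.04 in the 3 pairs, and the test value for fewer macrophages was -0.61. C1qa had a log2 level of 9.27 in FBS at 4 weeks and 5.80 in FFV, 9.46 and 5.81 in GMTMM iCMs and 11.60 in MEFs, and a sort for GFP would be expected to remove macrophages from the GMT iCMs. Of the 13 measured genes 0 are held by another list. Array scaling or background correction left the median of the markers at -0.57 or lower at 4 weeks and in GMTMM iCMs and is not a likely source there. At 2 weeks the FFV median depended on the setting. It was -0.18 with the surround subtracted, -0.23 with median scaling, -0.44 with an offset of 16, -0.97 with a floor and -0.96 in the value table.

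Glycolysis genes were lower in both media without serum. The loss of macrophages would bring down their own glycolysis transcripts. At 2 weeks the macrophage median in FFV was -0.24 and the glycolysis medians in FFV and SF were -0.44 or lower. That macrophage median depended on the setting, at -0.44 with an offset of 16, -0.97 with a floor and -0.96 in the value table. With the floor the macrophage medians in the 3 FFV pairs were -0.97, -2.42 and -5.26 and the glycolysis medians -0.44, -0.46 and -0.60. Glycolysis thus did not fall in step with the markers, but a part from macrophages stays open. Lower activity of the hypoxia factor HIF may contribute, since 10 measured hypoxia targets had medians of -0.24 to -0.66 in the 5 pairs, 4 of them at or under -0.3, with a middle value of -0.51. FFV and SF share an FBS array at each GMT time, so these pairs are not independent. At least 2-fold higher and lower in FFV were 1 and 0 targets at 2 weeks, 0 and 2 at 4 weeks and 1 and 1 in GMTMM iCMs. In SF these were 0 and 0 at 2 weeks and 0 and 4 at 4 weeks. Array scaling left the medians at -0.40 or lower in all 5 pairs with median scaling and in the value table and is not a likely source. Background correction stays open for FFV at 4 weeks alone, where the median was -0.19 with the surround subtracted, the other 14 of the 15 values under 3 other backgrounds being -0.41 or lower.

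Sarcomere genes were lower in MT and GMTMM iCMs than in GMT iCMs. Dilution of cells like the GMT iCMs by others would lower all sarcomere genes by a like share, but in MT iCMs the shares of 15 genes ran from 0.22% to 193% (median 9.98%), against 47.1% to 136% (median 86.9%) between the GMT arrays in FFV. The excess span was 2.72 for MT iCMs, more than dilution alone would give between arrays of 1 series. The MT array is of another series than the GMT arrays, and no like cells were measured in both. A difference between series could widen the span too, so dilution is not settled. The excess span was 1.25 for GMTMM iCMs, whose shares ran from 0.064% to 33.1% (median 1.72%), and there dilution could not be told apart. The array series could not be excluded either, as the MEF and TTF arrays, which differ by -0.0051 in sarcomere genes, are both outside the series of the GMT iCMs. Nor could the sort of the GMT iCMs or the time in culture, as the labels give neither for the MT and GMTMM iCMs. The fibroblast source could not be excluded either. The GMTMM iCMs came from TTFs and the GMT iCMs from MEFs, and the source of the MT iCMs is not stated here.

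For FFV against FBS, 1 of 10 splits of the arrays reached the count of the real one, namely the real one itself with 6, and the highest other called 0. The fits of the other splits hold no term for FFV against FBS. A medium effect therefore adds to their scatter and can lower their counts. A level cannot be set from 10 splits either. For time the real split called 0, so each of the 10 splits reaches it and their number decides nothing. The highest other count, 77, came from 2 splits in which only the FBS arrays part by time within their medium, so these calls rest on 1 FBS array at each time, with the spread taken from the SF and FFV arrays.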
